A study of Danio rerio with 20 samples.

How the data were processed

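Gene expression was measured in the intestine of adult female zebrafish kept at 25 °C, with 4 arrays in each of 5 groups. One group was untreated and kept for 21 days. The other 4 received antibiotics for 7 days, recovered for 1 day, were given intestinal microbes of zebrafish or goldfish, and then ate the food of either species for 14 days. Per the labels' protocols, 500 ng of total RNA were labelled with Cy3 and hybridized to 1-colour Agilent arrays. Whether an RNA came from 1 fish or a pool is not given. The groups were housed separately, so a p-value here measures the spread between these samples and cannot separate a treatment from its tank.

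The scanner files hold the spot intensity as deposited. Per the file headers, the images were read with Feature Extraction 11.0.1.1 and protocol GE1_1100_Jul11 from a scanner at 20 bits, which subtracted the background and corrected spatial trends within each array, with no normalization between arrays. The deposited flags of 0 or 1 per spot mark signal well above background, saturation and outlier spots, per the file headers. Each array has 45220 spots, of which 43803 are not controls, for 43603 probes. The 300 spots marked as outliers were left out, and 0 spots were saturated.

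The 75th percentile of the signal, used as the measure of brightness, ran from 199.6 on replicate 4 of goldfish food with zebrafish microbes to 1500.5 on replicate 2 of zebrafish food with goldfish microbes. Spots well above background made up 78.3% to 90.4% of an array. Repeated spots of 1 probe had a coefficient of variation of 5.29% to 8.67%, except on replicate 2 of goldfish food with goldfish microbes (17.7%).

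The series also holds a table of processed values by sample, intensity on a linear scale as deposited, whose normalization and centring are not given in the sources used here. The column medians were 135, 52.2, 89.5 and 65.5 for untreated fish, 112, 52.1, 41.1 and 88.15 for zebrafish food with zebrafish microbes, and 195, 113, 104 and 41.7 for zebrafish food with goldfish microbes. They were 144, 73.5, 142 and 34.2 for goldfish food with zebrafish microbes and 94.3, 166, 76.4 and 88.45 for goldfish food with goldfish microbes. Each column matched 1 scanner file of its own group best (correlation 0.803 to 0.997, second lowest 0.976), but for 13 of 20 columns the replicate number differed. These values served as an alternative, and the scanner files were used for the results. No sample column was left unused.

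Values were computed as log2 of the deposited processed signal minus the 75th percentile of each array, and spots of 1 probe were averaged. A probe was tested if it was well above background on at least 4 of 20 arrays, which kept 40300 probes, of which 29099 were well above background on all 20. Of the 43603 probes 25854 matched exactly 1 gene symbol (13293 genes) and 17749 matched none. Symbols came from a gene table of assembly GRCz12tu, used for names alone, while the array header names build danRer7 (Zv9), so no coordinates are given. Of the 12741 genes tested 7453 had several probes, and a gene was represented by the probe with the highest mean.

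All 20 arrays entered 1 linear model with a mean per group (limma 3.58.1 in R 4.3.3, empirical Bayes, 15 residual degrees of freedom; with the packages jsonlite 2.0.0 and data.table, version 1.17.8). There were 13 comparisons, each with Benjamini-Hochberg adjustment over all probes at 0.05. The effect of the procedure is zebrafish food with zebrafish microbes minus untreated. The effects of food and of microbiome are the means of the differences within the levels of the other factor, and the interaction is the difference of the food effects. The other comparisons are between single groups, or all treated groups against untreated.

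Gene lists (24 of functions and 12 of cell types, 36 in all, from general knowledge) were tested with camera of limma, with its preset correlation of 0.01 and, beside it, an estimated correlation, with at least 5 genes per list and adjustment over the 36 lists. These tests use genes with a value on all 20 arrays, so in 6 lists 1 member with a left-out spot was dropped. Members were also adjusted over the list alone. Because the arrays lie on 5 slides of 4 arrays, each without 1 of the groups, values with the slide as a block (the slide block) and within slides are given. On 4 of the slides 1 treated group is missing, so a value of food or microbiome within them mixes the 2 factors. A list was also reduced to 1 score per array, the mean of its genes after each gene's mean over arrays was subtracted, and tested with limma. This test was chosen after the data were seen.

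Genes are named by rule. In each main comparison these are the 12 with the largest rise and the 12 with the largest fall among genes past the threshold and above background on both sides, up to 3 per direction that were above background on 1 side alone, and up to 4 members of each list called or with a called member. If fewer than 10 genes passed, the 10 with the smallest p are given as values. In the other comparisons these are the 3 largest per direction. Some genes that the rule selects are not reported here. Of 360 pairs of gene and comparison 228 had another probe, and in 213 all probes had the same sign. In 1, cyp7a1 in the comparison of microbiomes, another probe was called in the opposite direction, and that gene is given no direction. A gene at background on 1 side has a bound in place of a difference. The groups, comparisons, tests, lists, naming rule and the other settings listed next were set before the data were examined.

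The other settings were normexp background correction (offset 50), quantile normalization, no filter and a stricter filter on dim probes, the slide as a block, the replicate number as a block, the processed values of the series, the compared groups alone in the fit, and each array left out in turn. Because the mean signal is not in the files, normexp was run on the median signal. Plain subtraction of the background and a fit without 2 arrays were added after the data were seen.

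The steps were tested on 40100 simulated probes, 50 per size changed by 0.5, 1, 2 and 3 log2 units. Of these 0, 5, 22 and 42 were recovered for the procedure (0 false calls of 69), 0, 11, 33 and 41 for the microbiome (2 of 87), 1, 16, 33 and 44 for the food (4 of 98), and 0, 0, 12 and 27 for the interaction (2 of 41). The combined change gave 0, 0, 23 and 40 (1 of 64). The microbiome gave 0, 4, 21 and 37 (4 of 66) on zebrafish food and 0, 7, 29 and 41 (6 of 83) on goldfish. Food gave 0, 4, 25 and 38 (2 of 69) with zebrafish microbes and 0, 4, 33 and 41 (2 of 80) with goldfish microbes. Against untreated fish, goldfish microbes gave 0, 2, 23 and 33 (5 of 63) and goldfish food 0, 2, 26 and 37 (1 of 66). Both changes gave 0, 1, 22 and 38 (5 of 66), and all treated groups 3, 10, 36 and 45 (6 of 100). With 12666 independent genes 0 of 36 lists were called without change and the 1 shifted list was, so correlation was not tested.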

Results

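Intestinal RNA of adult female zebrafish was measured on 1-colour arrays in 5 groups of 4. One group was untreated. The other 4 were given antibiotics, then intestinal microbes of zebrafish or goldfish, and zebrafish or goldfish food, in 4 combinations. Signal well above background was found on at least 4 arrays for 40300 probes, of which 24585 carried the name of 1 of 12741 genes. The correlation between arrays of the same group ran from 0.876 to 0.974 (median 0.945), and the median between arrays of different groups was 0.935. Differences are given in log2 with their standard error, and levels as log2 signal minus the 75th percentile of the array with the SD over 4 arrays. For each gene the arrays on the treated side that lay beyond the mean of the other side were counted. Every gene said to have risen or fallen did so in all of them (4 of 4, 8 of 8 or 16 of 16) except where another number is given. Calls said to be lost in a number of fits were lost in fits that each left out 1 of the arrays compared.

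Antibiotics followed by a zebrafish microbiome on unchanged food (4 arrays) were first compared with no treatment (4 arrays). The gene cebpd, which encodes a transcription factor of the acute-phase response, fell by 2.06 ± 0.28 (adjusted p = 0.00873), from 4.49 ± 0.35 to 2.43 ± 0.54. The gene arl4ab, for a small GTPase, fell by 1.62 ± 0.24 (adjusted p = 0.0168), and spry4, for an inhibitor of receptor tyrosine kinase signalling, fell by 1.47 ± 0.23 (adjusted p = 0.0277). No named gene rose. In the group with both goldfish food and goldfish microbes cebpd stood at 4.71 ± 0.18. Among genes that did not pass, socs3a, for a feedback inhibitor of cytokine signalling, had a difference of -2.12 ± 0.38 (adjusted p = 0.0922), and ccr9a, for a chemokine receptor, -1.78 ± 0.34 (adjusted p = 0.131). The values of raraa, for a retinoic acid receptor, and of pvalb9, for a calcium-binding parvalbumin, were 1.79 ± 0.36 (adjusted p = 0.152) and 2.88 ± 0.58 (adjusted p = 0.157).

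In all, 11 probes passed in this comparison, 0 higher and 11 lower (1 higher and 9 lower after quantile normalization), and 2750 had an unadjusted p below 0.05. The slide block left 9 probes, of which 7 were among the 11. A fit of these 2 groups alone gave 19 probes, and cebpd and arl4ab each had an adjusted p of 0.126 in it. The count was 5 without untreated replicate 3, 1 without untreated replicate 4, and 6, 4, 2 and 6 without replicates 1, 2, 3 and 4 of the treated group. The call of cebpd was lost in 3 of the 8 fits that left out 1 of these arrays, that of arl4ab in 6 and that of spry4 in 8. The call of spry4 was also lost with the slide block and with the replicate block.

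Genes of the cell cycle had higher values after the treatment on 84 of 88 genes, with a median of 0.51, but 0 rose, 0 fell and 88 did not pass, and 0 rose adjusted over the list alone. The list passed camera with its preset correlation (adjusted p = 5.06e-18), with adjusted p = 0.407 with estimated correlation. Its difference with the slide block was 0.61 ± 0.23, and within 3 slides it ran from -0.34 to 0.96. Examples are gmnn, for geminin, a brake on DNA licensing (1.2 ± 0.34), and ccnb2, for cyclin B2 (1.67 ± 0.48). Markers of oocytes and ovary had a median of 0.77 in the same comparison (adjusted p = 3.60e-06, and 0.495 with estimated correlation; 1.62 ± 0.75 with the slide block). Egg-coat genes were among them, zp3b with 3.44 ± 0.88 and zp3 with 5.66 ± 1.88, and none passed. The liver list had a median of -0.85 but a mean of 0.19 and did not pass (adjusted p = 0.241).

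Lists of immune cells and of the clock had lower values. Acute inflammation had a median of -0.52 over 41 genes (adjusted p = 0.000198, and 0.407 with estimated correlation), with 0 genes fallen and 1 adjusted over the list alone, and -0.56 ± 0.24 with the slide block. Its members include hamp, for the iron hormone hepcidin (-2.30 ± 0.79), and mmp9, for a matrix metalloproteinase (-1.82). T and NK cell genes had a median of -0.49 (adjusted p = 0.000198, and 0.407 with estimated correlation), with 1 fallen adjusted over the list alone. Among them sla2b, for an adaptor of T cell signalling, had -1.07 ± 0.27. Clock genes had a median of -0.23 (adjusted p = 0.00423, and 0.407 with estimated correlation) with 0 fallen and 3 adjusted over the list alone. The clock repressor nr1d1 had -1.84 ± 0.40 (adjusted p = 0.206). These 3 lists were lower within each of 3 slides, and the call of the clock was lost in 1 of 8 fits.

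With the preset correlation, lower values were also found after the treatment for gluconeogenesis and glycolysis (median -0.17, adjusted p = 0.0195), neurons and glia (-0.37, 0.0131), endothelium (-0.27, 0.0131) and macrophages and neutrophils (-0.22, 0.04996). Higher values were found for the unfolded protein response (0.34, 0.00388) and the proteasome (0.16, 0.0351). Higher values for pancreatic digestive enzymes (0.35, 0.00795) and ribosomal proteins (0.28, 3.91e-05) reversed under quantile normalization. The adjusted p with estimated correlation was 0.407 for gluconeogenesis and 0.485 for neurons and glia, endothelium and the unfolded protein response. It was 0.635 for pancreatic enzymes and for macrophages and neutrophils, and 0.682 for ribosomal proteins and the proteasome. No member of these lists passed. The calls of the proteasome and of macrophages and neutrophils were each lost in 5 of 8 fits. Those of gluconeogenesis, neurons and glia, and endothelium were lost in 2, and those of pancreatic enzymes, ribosomal proteins and the unfolded protein response in 1. The proteasome call was also lost with quantile normalization and plain subtraction, and that of macrophages and neutrophils without 2 arrays (the dimmest and the one with the noisiest repeat spots).

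The food was compared over both microbiomes, with 8 arrays on goldfish food and 8 on zebrafish food. Genes of the cell cycle fell on goldfish food, 58 of 88 with 0 risen and 30 not passed, and 78 fell adjusted over the list alone. The cyclin gene ccnb1 fell by 2.21 ± 0.33 (adjusted p = 0.0011), tacc3, for a spindle protein, fell by 1.93 ± 0.26, and plk1, for a mitotic kinase, fell by 1.92 ± 0.26. The kinesin genes kif4 and kif11, of the mitotic spindle, had -1.79 ± 0.23 and -1.76 ± 0.24, with adjusted p = 0.000707 for these last 4 genes. The median of the list was -1.09 (adjusted p = 1.49e-55, and 0.0223 with estimated correlation). Its score per array differed by -1.10 ± 0.16 (adjusted p = 5.75e-05), by -1.11 ± 0.16 with the slide block, and by -1.33 to -0.82 within the 5 slides. The score was 0.60 ± 0.31 and 0.48 ± 0.21 on zebrafish food with zebrafish and goldfish microbes, -0.57 ± 0.37 and -0.56 ± 0.40 on goldfish food, and 0.05 ± 0.29 in untreated fish. The list of oocyte and ovary markers had a median of -0.40 in this comparison and did not pass (adjusted p = 0.0881; -0.66 ± 0.53 with the slide block).

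Genes of fat absorption and of the brush border rose on goldfish food. Of 31 genes of intestinal lipid absorption 9 rose, 0 fell and 22 did not pass, and 21 rose adjusted over the list alone. Among them were dgat2 and dgat1a, for enzymes of the last step of triglyceride synthesis (1.80 ± 0.32, adjusted p = 0.00343, and 1.14 ± 0.21, adjusted p = 0.00484), slc27a4, for a fatty acid transport protein (1.23 ± 0.24), and agpat2, for an acyltransferase (1.02 ± 0.20). The list median was 0.83 (adjusted p = 4.07e-12, and 0.0651 with estimated correlation), 0.79 ± 0.14 with the slide block and above 0 in 5 of 5 slides. Of 13 brush border hydrolase genes 5 rose, 0 fell and 8 did not pass, and 7 rose adjusted over the list alone. They included alpi.2, for intestinal alkaline phosphatase (1.82 ± 0.38, adjusted p = 0.011), naalad2, for a peptidase (1.64 ± 0.34), mep1a.2, for a subunit of the protease meprin (1.59 ± 0.21, adjusted p = 0.000707), and xpnpep2, for an aminopeptidase (1.35 ± 0.28). Their median was 0.64 (adjusted p = 1.60e-06, and 0.117 with estimated correlation), 0.85 ± 0.20 with the slide block. Of 22 carbohydrate and amino acid transporter genes 3 rose and 19 did not pass (10 rose adjusted over the list alone), with a median of 0.69 (adjusted p = 5.01e-05, and 0.0212 with estimated correlation) and 0.62 ± 0.11 with the slide block. The 3 were slc5a11, for a sodium-coupled transporter (0.84, 7 of 8 arrays), slc16a10, for an aromatic amino acid transporter (0.77), and slc3a2a, for an amino acid transporter subunit (0.70), whose calls were lost in 12, 9 and 12 of 16 fits and with the slide block. The other probe of slc16a10 had the opposite sign.

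Genes of xenobiotic response rose, 11 of 47 with 0 fallen and 36 not passed, and 25 rose adjusted over the list alone. Among them were abcg2c, for a drug efflux pump (1.6 ± 0.30, adjusted p = 0.00556), and cyp2n13, for a cytochrome P450 (1.34 ± 0.28, adjusted p = 0.0113). Others were sult1st3, for a sulfotransferase (1.33 ± 0.25, adjusted p = 0.00557), and ugt1a1, for a glucuronosyltransferase (1.22 ± 0.20, adjusted p = 0.00203). The list median was 0.75 (adjusted p = 1.21e-11, and 0.0212 with estimated correlation), 0.73 ± 0.12 with the slide block and 0.38 to 1.14 within slides. Genes of cholesterol synthesis and uptake fell, 14 of 26 with 0 risen and 12 not passed, and 22 fell adjusted over the list alone. The list median was -1.24 (adjusted p = 1.16e-16, and 0.0850 with estimated correlation), -1.19 ± 0.24 with the slide block and -2.35 to -0.36 within slides. The gene hmgcs1, for HMG-CoA synthase, fell by 1.94 ± 0.35 (adjusted p = 0.00389), cyp51, for a sterol demethylase, by 1.91 ± 0.41 (adjusted p = 0.0125), and fdft1, for squalene synthase, by 1.62 ± 0.33 (adjusted p = 0.00854). The LDL receptor gene ldlra fell by 1.24 ± 0.24 (adjusted p = 0.00605). Levels were lower in 6 of 8 arrays for hmgcs1, 5 for cyp51 and 7 for fdft1. The list score was 0.23 ± 0.70 on goldfish food with zebrafish microbes and -1.57 ± 0.20 with goldfish microbes.

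**Figure D1:**
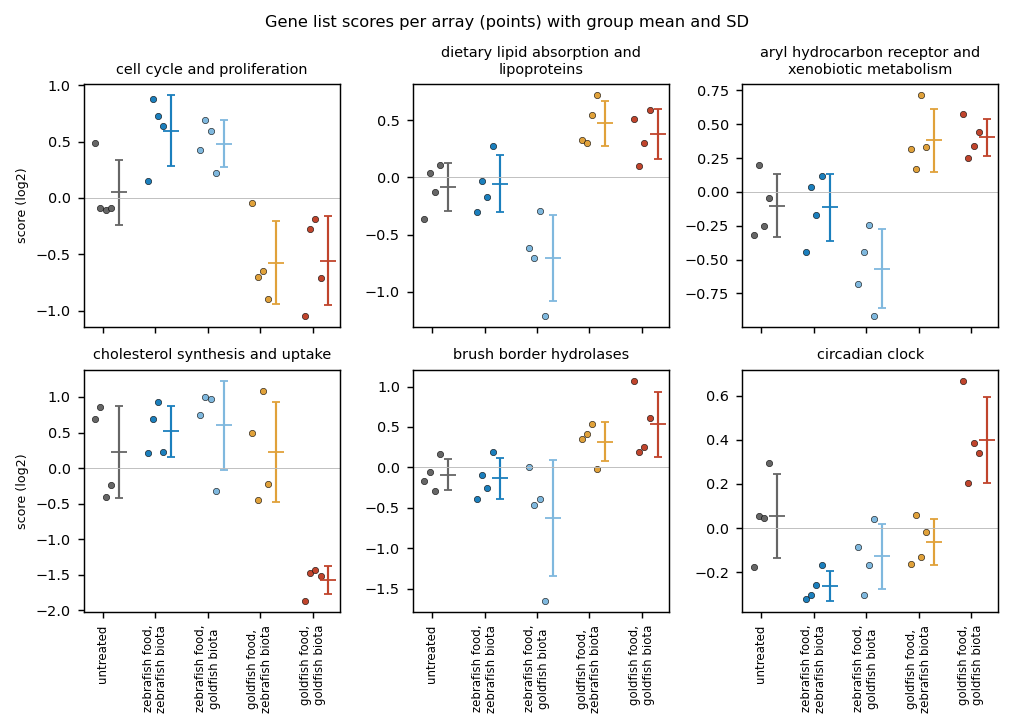
Scores of 6 gene lists on each array by group, where the y axis is the mean log2 level of a list relative to its mean over arrays, points are arrays and bars are the group mean and SD. Cell cycle scores were near -0.57 and -0.56 in the groups on goldfish food, and cholesterol scores were lowest (-1.57 ± 0.20) with both goldfish food and goldfish microbes.

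On goldfish food the retinol-binding protein gene rbp4l rose by 3.83 ± 0.71 (adjusted p = 0.00471) and nr0b2a, for a repressor of bile acid synthesis, by 2.74 ± 0.42 (adjusted p = 0.00132). The carboxypeptidase gene cpo rose by 2.40 ± 0.37 (adjusted p = 0.00132) and the glutamine synthetase gene glulc by 2.33 ± 0.47 (adjusted p = 0.00903). The parvalbumin gene pvalb9 rose by 3.44 ± 0.42 (adjusted p = 0.000707; all 7 arrays with a value), and the anion transporter genes slc13a3 and slc13a1 by 2.25 ± 0.47 and 1.90 ± 0.49. The arrestin gene saga, the lens crystallin gene crygm3, aadacl4, for an arylacetamide deacetylase-like protein, and the transcription factor gene glis3 rose by 2.39 ± 0.56, 2.26 ± 0.47, 2.03 ± 0.48 and 2.04 ± 0.53. Genes that fell include ifng1r, for an interferon gamma receptor (-2.62 ± 0.32, adjusted p = 0.000707), and irf8, for a transcription factor of macrophages (-2.51 ± 0.34, adjusted p = 0.000709). Others were gbp1, for an interferon-induced GTPase (-2.14 ± 0.30, adjusted p = 0.00084), and mxg, for an antiviral GTPase (-2.81 ± 0.55, adjusted p = 0.00689). The acute-phase gene saa fell by 2.74 ± 0.64 (adjusted p = 0.0197), the heat shock family gene hspa12a.3 by 2.69 ± 0.69, and the C2-domain gene doc2g by 1.98 ± 0.50. The histone gene hist1h2a11 fell by 2.24 ± 0.36 (adjusted p = 0.00191), and the sterol genes sqlea and lss by 2.19 ± 0.48 and 2.1 ± 0.49 (6 of 8 arrays each). The gene brinp3a.1, at background on zebrafish food, was at least 1.87-fold higher (adjusted p = 0.017), with 5 of 8 arrays above background. The calls of glis3, slc13a1, hspa12a.3, doc2g and aadacl4 were lost in 11, 8, 8, 9 and 1 of 16 fits, and another probe of glis3 had the opposite sign. The slide block ended those of saa, slc13a1, hspa12a.3 and doc2g. Plain subtraction ended those of saga, glulc, slc13a3, aadacl4, glis3, hspa12a.3 and doc2g, and the fit without 2 arrays those of saga, glis3 and hspa12a.3.

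**Figure D2:**
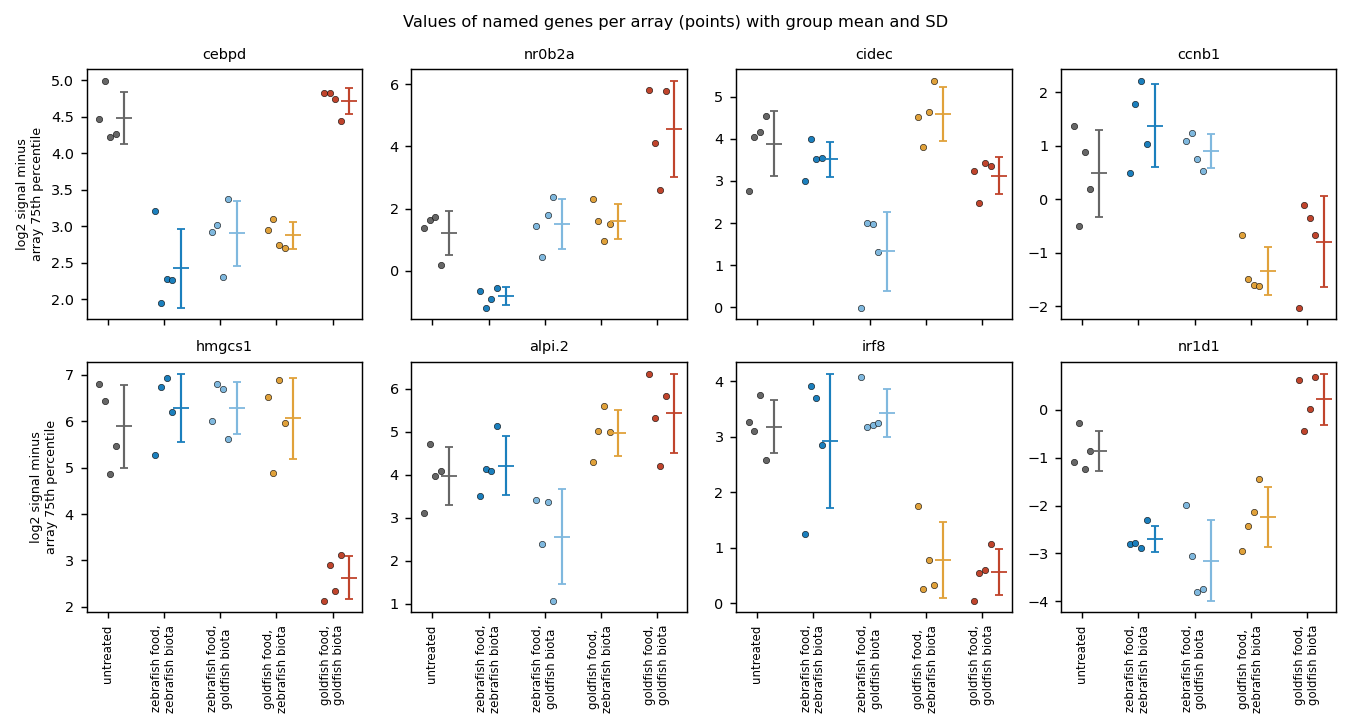
Level of 8 genes on each array by group, where the y axis is log2 signal minus the 75th percentile of the array, points are arrays and bars are the group mean and SD. The level of irf8 was 2.93 ± 1.21 and 3.43 ± 0.43 in the groups on zebrafish food after treatment and 0.78 ± 0.69 and 0.56 ± 0.41 in those on goldfish food.

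Few genes of the fixed lists of immune genes passed. Of 33 interferon and antigen presentation genes 4 fell, 0 rose and 29 did not pass. Those that fell include irf1b, for an interferon-induced transcription factor (-1.52 ± 0.24, adjusted p = 0.00154), socs1a, for a cytokine signalling inhibitor (-1.62 ± 0.26, adjusted p = 0.00184), and the invariant chain gene cd74a (-1.15, adjusted p = 0.0388; 7 of 8 arrays). That list had a median of 0.04 and a mean of -0.03 and did not pass (adjusted p = 0.148). Of 29 macrophage and neutrophil genes 1 rose, 3 fell and 25 did not pass (3 rose and 12 fell adjusted over the list alone). Their median was -0.61 (adjusted p = 5.01e-05, and 0.171 with estimated correlation) and the score differed by -0.43 ± 0.14 with the slide block. The complement genes c1qa and c1qc fell by 1.18 and 0.86, the protease gene ctss2.1 by 0.92 (7 of 8 arrays), and apoeb, for an apolipoprotein of macrophages, rose by 1.18 ± 0.26. Of 41 acute inflammation genes 1 fell (1 adjusted over the list alone), with a median of -0.27 (adjusted p = 0.0142, lost in 1 of 16 fits, and 0.380 with estimated correlation). Of 24 T and NK cell genes 2 fell, among them cd247l, for a T cell receptor chain (-1.32, adjusted p = 0.0479; 7 of 8 arrays), and the list did not pass (median -0.07, adjusted p = 0.0916). B cell genes had a median of -0.29 (adjusted p = 0.0849). Of the genes that fell here, the calls of cd74a, c1qa, c1qc, ctss2.1 and cd247l were lost in 12, 9, 4, 12 and 13 of 16 fits, and those of cd74a and c1qa with the slide block.

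Of 32 clock genes 7 rose, 1 fell and 24 did not pass on goldfish food, and 10 rose and 1 fell adjusted over the list alone. The clock repressor genes nr1d1, nr1d2b and per1b rose by 1.92 ± 0.28 (adjusted p = 0.00107; 7 of 8 arrays), 1.05 ± 0.18 (adjusted p = 0.00238) and 1.2 ± 0.24 (adjusted p = 0.00702), and tefa, for a clock output factor, by 1.21 ± 0.18 (adjusted p = 0.00119). The list median was 0.32 (adjusted p = 0.00104, and 0.0951 with estimated correlation), 0.35 ± 0.10 with the slide block. Of 14 adipose genes 5 rose, among them cideb, for a lipid droplet protein (1.36 ± 0.22, adjusted p = 0.00168), and cebpa, for a transcription factor (1.07 ± 0.20, adjusted p = 0.00532). Their median was 0.69 (adjusted p = 0.000284, and 0.0881 with estimated correlation). Of 21 genes of lysosome-rich enterocytes 2 rose, asah1b, for a ceramidase (1.31 ± 0.28), and scpep1, for a serine carboxypeptidase (0.91, lost in 10 of 16 fits), with a median of 0.50 (adjusted p = 0.00159, and 0.177 with estimated correlation). Of 28 fatty acid oxidation genes none passed (4 rose adjusted over the list alone), with a median of 0.40 (adjusted p = 0.00124, and 0.182 with estimated correlation), and pdk4, for a kinase that spares glucose, had 1.09 (adjusted p = 0.0662). Of 47 proteasome genes 5 fell and 42 did not pass (14 fell adjusted over the list alone), among them psma1 (-0.79) and psma4 (-0.75), for core subunits, with a median of -0.41 (adjusted p = 3.37e-10, and 0.183 with estimated correlation). The calls of psma1 and psma4 were lost with the slide block.

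Antioxidant genes were higher on goldfish food on 3 of 31, among them gclc, for the enzyme that starts glutathione synthesis (1.06), and prdx1, for a peroxiredoxin (1.05), each in 7 of 8 arrays. Their median was 0.35 (adjusted p = 0.00671, and 0.208 with estimated correlation). The unfolded protein response had a median of -0.21 over 38 genes with 1 fallen, calr3a, for a calreticulin (-0.73), and adjusted p = 0.0246 (adjusted p = 0.463 with estimated correlation; the list was lost in 4 of 16 fits). Liver markers had a median of -0.92 with 0 of 32 passed (adjusted p = 0.000284, and 0.503 with estimated correlation), -1.18 ± 0.65 with the slide block and -3.65 to -0.65 within slides. The egg yolk genes vtg2 and vtg4 had values of -3.85 ± 1.91 and -3.19 and did not pass. Lists that did not pass held single changes. The bile acid genes abcc2, for an export pump, and nr1i2, for a xenobiotic receptor, rose by 0.96 and 0.78 (list median 0.17, adjusted p = 0.107), and the call of nr1i2 was lost with plain subtraction. Of 27 gluconeogenesis and glycolysis genes 3 rose and 1 fell (adjusted p = 0.273), and pck1, for the enzyme that starts gluconeogenesis, rose by 1.56 ± 0.42 (adjusted p = 0.0423). Of 31 heat shock genes 2 rose, serpinh1b, for a collagen chaperone (0.95), and hsf2, for a heat shock factor (0.97, 7 of 8 arrays; list adjusted p = 0.396). Of 89 mitochondrial genes 2 rose and 1 fell (adjusted p = 0.0849). No member passed and the list did not pass for fatty acid and triglyceride synthesis (median 0.24, adjusted p = 0.338), ribosomal proteins (-0.06, 0.273), enteroendocrine cells (0.38, 0.0507), endocrine pancreas (0.39, 0.159), and goblet cells (0.10, 0.636). The same held for red blood cells (-0.09, 0.305), skeletal muscle (0.14, 0.791), neurons and glia (0.22, 0.351), endothelium (0.09, 0.482) and smooth muscle and stroma (-0.11, 0.166). Pancreatic digestive enzymes had a median of -0.05 and a mean of 0.02 (adjusted p = 0.401), and amino acid breakdown and urea cycle genes a median of 0.28 (adjusted p = 0.0653). The calls of prdx1, calr3a, pck1 and hsf2 were lost in 11, 13, 12 and 11 of 16 fits, and those of prdx1, calr3a and pck1 with the slide block.

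For the food, 1548 probes passed, 717 higher and 831 lower, which stood for 753 genes (352 higher, 401 lower). A block for the slide gave 1143, of which 1057 were among them. The count was 1001 without replicate 3 of zebrafish food with zebrafish microbes and 1002 without replicate 1 of goldfish food with goldfish microbes.

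**Figure D3:**
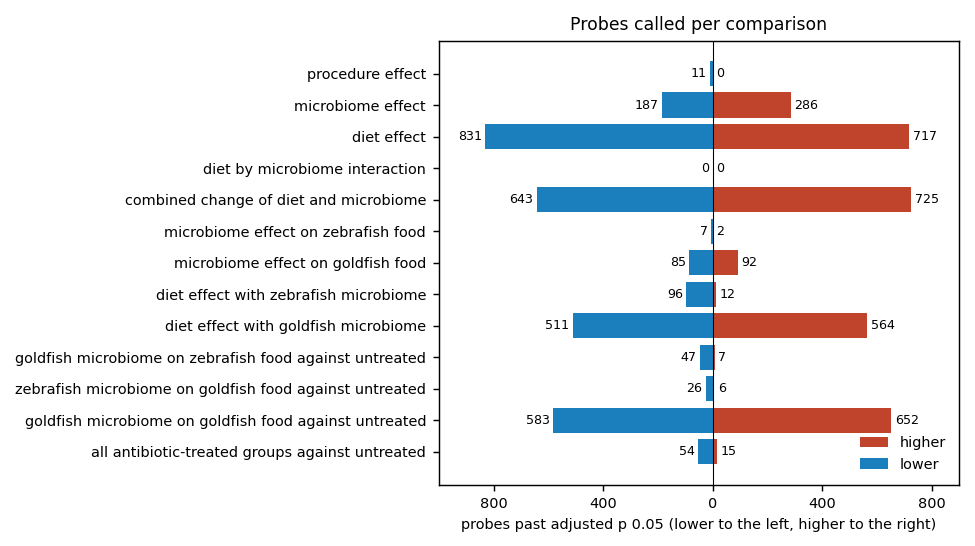
Probes called at an adjusted p below 0.05 in each of 13 comparisons, where the x axis is the number of probes and bars show those higher and those lower. Between foods 717 probes were higher and 831 lower on goldfish food, and 0 passed for the interaction of food and microbiome.

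The microbiome was compared over both foods, with 8 arrays given goldfish and 8 given zebrafish microbes. The mitochondrial carrier genes slc25a25b and slc25a25a fell with goldfish microbes by 1.90 ± 0.22 and 1.74 ± 0.21 (adjusted p = 0.00226 for both), and ugt5a1, for a glucuronosyltransferase, by 2.89 ± 0.47 (adjusted p = 0.0146). The lipid droplet gene cidec fell by 1.83 ± 0.33 (adjusted p = 0.0154) and pck1 by 1.98 ± 0.42 (adjusted p = 0.0304). The transcription factor gene cebpa fell by 1.39 ± 0.20 (adjusted p = 0.00904) and cyp1a, for a P450 induced by aryl hydrocarbons, by 1.44 ± 0.26 (adjusted p = 0.0183). The bile acid repressor gene nr0b2a rose by 2.66 ± 0.42 (adjusted p = 0.0131). The call of cyp1a was lost in 1 of 16 fits, and those of cyp1a and pck1 with the slide block. The level of nr0b2a was -0.83 ± 0.29 with zebrafish food and microbes but 0.17 to 1.72 in untreated fish. It was 1.51 ± 0.81 with goldfish microbes, 1.59 ± 0.56 with goldfish food and 4.57 ± 1.55 with both.

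Other genes that rose with goldfish microbes were klhl24b, for a ubiquitin ligase adaptor (2.53 ± 0.46, adjusted p = 0.0174), and ypel3, for a growth inhibitor (2.43 ± 0.38, adjusted p = 0.013). They also include hbp1, for a repressor of proliferation (1.92 ± 0.32, adjusted p = 0.0147), and tp53inp1, for a p53-induced protein (1.92 ± 0.31, adjusted p = 0.0134). The gene gbp, for a protein that binds the kinase GSK-3 (2.01 ± 0.34, adjusted p = 0.0147), arl16, for a small GTPase (1.93 ± 0.31, adjusted p = 0.0134; lost with plain subtraction), and the tubulin gene tuba2 (1.89 ± 0.33, adjusted p = 0.0152) also rose. The ATP receptor gene p2rx4b, bbc3, for a cell death activator, and coq8aa, for a kinase of coenzyme Q synthesis, rose by 1.83 ± 0.43, 1.67 ± 0.39 and 1.53 ± 0.32 (7 of 8 arrays for coq8aa). Their calls were lost in 11, 12 and 8 of 16 fits, and those of p2rx4b and bbc3 with the slide block. Genes that fell were hspa13, for a chaperone (-2.22 ± 0.49, adjusted p = 0.0359), rab33ba, for a Golgi GTPase (-1.73 ± 0.32, adjusted p = 0.0176), and higd1a, for a mitochondrial hypoxia protein (-1.58 ± 0.30, adjusted p = 0.021). The calls of hspa13, pck1, rab33ba and higd1a were lost in 8, 6, 1 and 3 of those fits, and that of hspa13 with the slide block. The cytokine gene il17a/f2 was at least 3.70-fold lower (adjusted p = 0.0359), with 8 of 8 arrays with zebrafish microbes above background.

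Of 26 cholesterol genes 3 fell with goldfish microbes, 0 rose and 23 did not pass (14 fell adjusted over the list alone). The 3 were sqlea, for squalene epoxidase (-1.99 ± 0.48, adjusted p = 0.0494; 5 of 8 arrays), hmgcs1 (-1.72 ± 0.35, adjusted p = 0.0264; 6 of 8 arrays), and hmgcra, for HMG-CoA reductase (-1.58 ± 0.35, adjusted p = 0.0394; 5 of 8 arrays). Their calls were lost in 11, 6 and 10 of 16 fits and with the slide block, that of hmgcra also with the replicate block. On zebrafish food the list score did not fall (0.52 to 0.60 with goldfish microbes). The list median was -0.86 (adjusted p = 6.75e-09, and 0.310 with estimated correlation), -0.87 ± 0.24 with the slide block (adjusted p = 0.0927) and -1.72 to 0.41 within slides. Of 38 genes of the unfolded protein response 2 fell and 36 did not pass (7 fell adjusted over the list alone), manf, for a secreted stress factor (-1.12 ± 0.23, adjusted p = 0.0289), and dnajb9a, for a chaperone of the endoplasmic reticulum (-1.18 ± 0.27, adjusted p = 0.0443). That list had a median of -0.32 (adjusted p = 7.15e-06, and 0.304 with estimated correlation), was -0.34 ± 0.11 with the slide block and was lower within 5 of 5 slides. The calls of manf and dnajb9a were lost in 7 and 13 of 16 fits and with the slide block. Of 31 lipid absorption genes none passed (3 fell adjusted over the list alone), with a median of -0.45 (adjusted p = 0.000139, and 0.399 with estimated correlation) and -0.40 ± 0.14 with the slide block. The droplet coat gene plin2 had -1.78 (adjusted p = 0.0615) and mttp, for the protein that loads lipoproteins, -0.90 (adjusted p = 0.0681).

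Clock genes had a median of 0.22 with goldfish microbes (adjusted p = 0.00172, and 0.304 with estimated correlation), 0 of 32 passed and 3 rose adjusted over the list alone. Markers of endothelium were higher on 21 of 21 genes (median 0.37, adjusted p = 0.000369, and adjusted p = 0.310 with estimated correlation). Those of smooth muscle and stroma had a median of 0.48 (adjusted p = 0.000139, and 0.310 with estimated correlation), and no gene of either list passed. Examples are clec14a, for an endothelial lectin (0.84), flt1, for a VEGF receptor (0.60, with 1 of 2 other probes of the opposite sign), and myl9b, for a myosin light chain (0.74). With the slide block the 3 lists differed by 0.28 ± 0.10, 0.30 ± 0.10 and 0.40 ± 0.16. As 1 score per array, clock, endothelium, cholesterol and unfolded protein response each had an adjusted p of 0.0349, and each had 0.0927 with the slide block. Oocyte and ovary markers had a median of -0.46 (adjusted p = 0.448), liver markers 0.22 (adjusted p = 0.752) and skeletal muscle markers 0.00.

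Antioxidant genes had a median of -0.27 with goldfish microbes (adjusted p = 0.00561, and 0.349 with estimated correlation), with prdx5 risen by 0.90 and gclm, for a subunit of the enzyme that starts glutathione synthesis, fallen by 1.13 ± 0.20 (adjusted p = 0.0152). Heat shock genes had a median of -0.27 (adjusted p = 0.00680, and 0.304 with estimated correlation), with the co-chaperone gene bag3 fallen by 1.09 ± 0.19 (adjusted p = 0.0152) and serpinh1b by 0.89 (adjusted p = 0.0321). Ribosomal protein genes (median -0.20, adjusted p = 0.00208), mitochondrial genes (-0.20, 1.01e-05), proteasome genes (-0.26, 0.000139) and interferon genes (-0.18, 0.0477) had lower values, with adjusted p = 0.872, 0.666, 0.666 and 0.767 with estimated correlation. The call of the interferon list was lost in 10 of 16 fits and with the slide block, and that of ribosomal proteins in 3. Quantile normalization ended the calls of the antioxidant, heat shock, ribosomal, mitochondrial and interferon lists. Single genes of the last lists that fell were ndufa4b, of the respiratory chain (-1.05, adjusted p = 0.0304), and psmd11b, of the proteasome lid (-0.57, adjusted p = 0.0494). Of 47 xenobiotic genes 1 rose, ahr2, for an aryl hydrocarbon receptor (0.91 ± 0.22, adjusted p = 0.0494), and 2 fell, and the list did not pass (median -0.11, adjusted p = 0.0607). The calls of prdx5, serpinh1b, ndufa4b, psmd11b and ahr2 were lost in 11, 9, 7, 14 and 12 of 16 fits, and all but that of ndufa4b with the slide block. Cell cycle genes had a median of -0.01 (adjusted p = 0.399).

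For the microbiome, 473 probes passed, 286 higher and 187 lower (70 higher and 85 lower after plain subtraction), which stood for 252 genes. A block for the slide gave 157, of which 140 were among them, and 252 passed after quantile normalization. A fit of the 4 treated groups alone gave 145 probes. The count was 99 and 83 without replicates 2 and 3 of zebrafish food with zebrafish microbes, and 126 without replicate 1 of zebrafish food with goldfish microbes. Without replicates 1, 2, 3 and 4 of goldfish food with zebrafish microbes it was 171, 238, 159 and 823, and without replicates 1 and 4 of goldfish food with goldfish microbes it was 102 and 193. Without the 2 arrays named above it was 977.

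**Figure D4:**
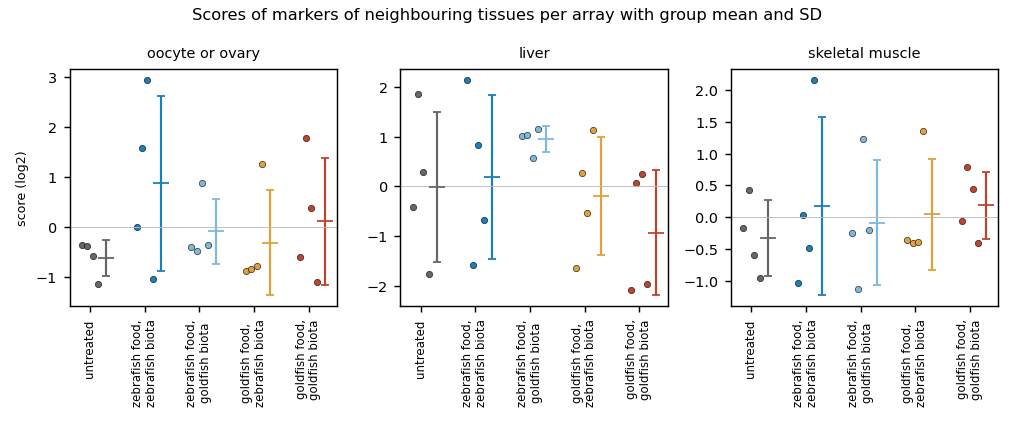
Scores of 3 marker lists of other tissues on each array by group, where the y axis is the mean log2 level of a list relative to its mean over arrays, points are arrays and bars are the group mean and SD. Replicate 4 of goldfish food with zebrafish microbes had the highest oocyte and ovary score of its group (1.25) and a skeletal muscle score of 1.36.

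Whether the effect of the food differed between the microbiomes was tested on 16 arrays. No probe passed in limma (smallest adjusted p = 0.139), and 3703 had an unadjusted p below 0.05. Smallest in p were pvalb9, with 5.39 ± 0.85 (adjusted p = 0.139), and nfil3-5, for a clock-linked repressor, with -3.33 ± 0.55 (adjusted p = 0.139). The sterol genes fdps, for farnesyl diphosphate synthase, hmgcs1 and cyp51 had -3.96 ± 0.74 (adjusted p = 0.201), -3.43 ± 0.70 (adjusted p = 0.233) and -3.75 ± 0.82. The level of fdps was 3.35 ± 0.46 and 4.19 ± 0.83 on zebrafish food with zebrafish and goldfish microbes, and 3.65 ± 1.2 and 0.53 ± 0.49 on goldfish food. The clock gene nr1d1 had 2.92 ± 0.56 (adjusted p = 0.209), cyp2p6, for a cytochrome P450, 2.68 ± 0.54 (adjusted p = 0.222), rergla, for a Ras-like protein, -2.17 ± 0.40 (adjusted p = 0.201), and hamp -4.74 ± 1.12 (adjusted p = 0.302). The median of all probes was -0.11, and it moved by 0.13 to 0.02 after quantile normalization and by 0.15 to 0.03 after plain subtraction.

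In the interaction, genes of cholesterol synthesis and uptake had a median of -1.75 (adjusted p = 8.15e-14, and 0.281 with estimated correlation), with 0 fallen and 13 fallen adjusted over the list alone. As 1 score per array the value was -1.89 ± 0.51 (adjusted p = 0.0283), and -1.68 ± 0.48 with the slide block (adjusted p = 0.0621). Pancreatic digestive enzymes had a median of 1.65 (adjusted p = 2.17e-11, and 0.281 with estimated correlation), with 0 risen and 11 risen adjusted over the list alone, among them cela1.3, for an elastase (3.0), and cpa4, for a carboxypeptidase (2.09). Their score differed by 1.53 ± 0.38 (adjusted p = 0.0283), and by 1.53 ± 0.42 with the slide block (adjusted p = 0.0621). Mitochondrial genes (median 0.56, adjusted p = 1.95e-14), lipid absorption (0.59, 4.41e-05), brush border hydrolases (0.66, 0.000916), xenobiotic response (0.52, 0.000916), fatty acid oxidation (0.44, 0.00238) and clock genes (0.45, 0.0102) had higher values. Acute inflammation (-0.71, 0.00140), T and NK cells (-0.53, 0.0139) and macrophages and neutrophils (-0.36, 0.0384) had lower values. The adjusted p with estimated correlation was 0.281 for these lists except brush border hydrolases (0.302) and macrophages and neutrophils (0.688). The last list was lost in 8 of 16 fits and with the slide block, T and NK cells in 2 and with plain subtraction, and fatty acid oxidation with quantile normalization. Markers of oocytes and ovary had a median of 1.51 (adjusted p = 0.00324, lost in 2 of 16 fits, and 0.788 with estimated correlation; 1.29 ± 1.06 with the slide block), and those of liver -2.22 (adjusted p = 0.000161, and 0.688 with estimated correlation; -1.86 ± 1.3). The 1 slide that held all 4 treated groups, with 1 array of each and so without an error, gave -0.75 for the cholesterol score and 0.72 for the pancreatic score. Leaving out 1 array gave 0 to 3 probes, with 2 without replicate 1 and 3 without replicate 3 of zebrafish food with goldfish microbes, 2 without replicate 2 of goldfish food with zebrafish microbes and 1 without replicate 4 of goldfish food with goldfish microbes. The named genes among them were pvalb9 (5.96 and 5.83 by 2 probes), cdo1, for an enzyme of cysteine breakdown (2.43), and fdps (-4.53).

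The food was also compared within each microbiome (4 arrays against 4). With zebrafish microbes ccnb1, ccnb2 and cdc20, of the division machinery, fell on goldfish food by 2.72 ± 0.46 (adjusted p = 0.0212), 2.62 (adjusted p = 0.0275) and 2.61 (adjusted p = 0.0475), and gclc rose by 1.83 ± 0.32 (adjusted p = 0.0246). All 4 calls were lost in 6 of 8 fits and with the slide block. Cell cycle genes fell on 15 of 88 (62 adjusted over the list alone), with a median of -1.08 (adjusted p = 1.28e-50, and 0.0476 with estimated correlation) and -1.22 ± 0.23 with the slide block. Markers of oocytes and ovary had a median of -0.63. With goldfish microbes 26 cell cycle genes fell (63 adjusted over the list alone), with a median of -1.07 (adjusted p = 0.0742 with estimated correlation). There pvalb9 rose by 6.14 ± 0.62 (adjusted p = 0.000311; all 3 arrays with a value, against 4), gstp1.1, for a glutathione transferase, by 5.05 (adjusted p = 0.0335; lost in 6 of 8 fits and with the slide block), and saa and sqlea fell by 4.93 ± 0.90 (adjusted p = 0.00805) and 3.96 ± 0.68 (adjusted p = 0.00629). Of the cholesterol genes 15 fell (21 adjusted over the list alone; median -2.21, adjusted p = 0.0581 with estimated correlation; -2.02 ± 0.34 with the slide block). Of the xenobiotic genes 11 rose (21 adjusted over the list alone; median 0.98, adjusted p = 0.0423 with estimated correlation), and of the lipid absorption genes 8 rose (24 adjusted over the list alone; median 1.28, adjusted p = 0.0581 with estimated correlation).

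Between foods 108 probes differed with zebrafish microbes (12 higher, 96 lower on goldfish food) and 1075 with goldfish microbes (564 higher, 511 lower). With the slide block the counts were 0 and 618. The first was 0 without replicate 2 or 3 of zebrafish food with zebrafish microbes, 3 without its replicate 4, and 0 without replicate 2, 3 or 4 of goldfish food with zebrafish microbes. The second was 536 and 697 without replicates 2 and 4 of zebrafish food with goldfish microbes, and 275 and 545 without replicates 1 and 4 of goldfish food with goldfish microbes. Fits of the 2 groups alone gave 2 and 30. Both lists of probes held 57 of the same probes, all 57 with the same sign, where 2.88 were expected from the sizes of the lists. Across the 40300 probes the correlation of the 2 effects was 0.144 (rank correlation 0.101), and 52.5% had the same sign. The median of all probes with zebrafish microbes moved by -0.13 to -0.03 after plain subtraction.

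The microbiome was also compared within each food (4 arrays against 4). On zebrafish food pvalb9 fell with goldfish microbes by 4.05 ± 0.58 (adjusted p = 0.0406), slc25a25b by 1.98 ± 0.32 and slc25a25a by 1.81 ± 0.29 (adjusted p = 0.0422 for both). These 3 calls were lost in 6, 7 and 7 of 8 fits, that of slc25a25a with the slide block, and the only other probe of slc25a25b had the opposite sign. On that food markers of oocytes and ovary had a median of -0.89 and those of liver 1.36. On goldfish food hmgcs1 fell by 3.44 ± 0.49 (adjusted p = 0.0109), cyp51 by 3.51 (adjusted p = 0.0151) and sqlea by 3.76 (adjusted p = 0.0216), and ypel3, nr0b2a and klhl24b rose by 3.01 (adjusted p = 0.0207), 2.98 (adjusted p = 0.0335) and 3.27 (adjusted p = 0.0333). The calls of hmgcs1, cyp51, sqlea, ypel3, nr0b2a and klhl24b were lost in 0, 3, 3, 5, 6 and 6 of 8 fits, and those of sqlea, ypel3 and nr0b2a with the slide block. There 7 of 26 cholesterol genes fell (19 adjusted over the list alone), with a median of -1.61 (adjusted p = 4.42e-18, and 0.158 with estimated correlation). As 1 score per array that list differed by -1.80 ± 0.36 (adjusted p = 0.00319), and by -1.70 ± 0.34 with the slide block. Of the clock genes 2 rose and 1 fell (9 and 2 adjusted over the list alone; median 0.55, adjusted p = 0.158 with estimated correlation).

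Between microbiomes 9 probes differed on zebrafish food, 2 higher and 7 lower (0 and 6 after quantile normalization, 5 and 8 in the processed values of the series, 0 and 5 after plain subtraction), and 177 on goldfish food, 92 higher and 85 lower. With the slide block the counts were 5 and 57, and fits of the 2 groups alone gave 0 and 0. The first was 0 without replicate 2, 3 or 4 of zebrafish food with zebrafish microbes and 2, 0, 45 and 0 without replicates 1, 2, 3 and 4 of zebrafish food with goldfish microbes. The second was 32, 59 and 17 without replicates 1, 2 and 3 of goldfish food with zebrafish microbes, and 23 and 58 without replicates 1 and 4 of goldfish food with goldfish microbes. Across probes the 2 effects had a correlation of -0.0196 (rank correlation 0.0205), and 51.0% had the same sign. The probes in both lists numbered 2, where 0.0395 were expected. The median of all probes on zebrafish food moved by -0.10 to -0.01 after plain subtraction.

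Goldfish food with goldfish microbes was compared with zebrafish food with zebrafish microbes (4 arrays against 4). The repressor gene nr0b2a rose by 5.40 ± 0.59 (adjusted p = 0.000724), klhl24b by 3.28 ± 0.65 (adjusted p = 0.0141) and tnni1c, for a troponin, by 3.36 ± 0.82 (adjusted p = 0.033; lost in 6 of 8 fits). The chemokine gene ccl19a.2 fell by 4.40 ± 0.98 (adjusted p = 0.0218), sqlea by 4.18 ± 0.68 (adjusted p = 0.00665) and hmgcs1 by 3.66 ± 0.49 (adjusted p = 0.00436). The calls of klhl24b and ccl19a.2 were lost in 3 of those fits each. Of the cholesterol genes 15 fell (21 adjusted over the list alone; median -2.14) and of the cell cycle genes 30 (68 adjusted over the list alone; median -1.15), while 7 clock genes rose and 1 fell (12 and 2 adjusted over the list alone; median 0.78), each with adjusted p = 0.0918 with estimated correlation. In all 1368 probes passed, 725 higher and 643 lower (293 and 419 after plain subtraction), and 902 with the slide block. The count was 321, 220 and 842 without replicates 2, 3 and 4 of zebrafish food with zebrafish microbes, and 214 and 739 without replicates 1 and 4 of goldfish food with goldfish microbes.

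Treated groups with a changed microbiome, food or both were compared with untreated fish (4 arrays against 4). With goldfish microbes on zebrafish food pck1 fell by 4.43 ± 0.59 (adjusted p = 0.00225), from 4.71 ± 0.31 to 0.28 ± 1.4, plin2 fell by 3.47 ± 0.64 (adjusted p = 0.0405) and ugt5a1 by 3.47 (adjusted p = 0.0485). The calls of plin2 and ugt5a1 were lost in 6 of 8 fits. With zebrafish microbes on goldfish food ifng1r fell by 2.68 ± 0.46 (adjusted p = 0.0357), casp6b.2, for a caspase, by 2.72 (adjusted p = 0.0425), and pvalb9 rose by 3.63 ± 0.58 (adjusted p = 0.027). These 3 calls were lost in 6, 7 and 6 of 8 such fits, and with the slide block. With both, sqlea fell by 4.06 ± 0.68 and the chemokine gene ccl19a.1 by 4.03 ± 0.67 (adjusted p = 0.00547 for both), while pvalb9 rose by 4.97 ± 0.62 (adjusted p = 0.00165; all 3 arrays with a value, against 4) and slc46a1, for a folate transporter, by 4.24 (adjusted p = 0.0353; lost in 6 of 8 such fits). There 11 cholesterol genes fell (21 adjusted over the list alone; median -1.6, adjusted p = 0.308 with estimated correlation). With all 16 treated arrays against 4 untreated, pck1 fell by 2.40 ± 0.46 (adjusted p = 0.0477), cldnb, for a tight junction claudin, by 2.28 ± 0.43 (adjusted p = 0.0429), and guca1c, for a guanylate cyclase activator, by 3.10 ± 0.60 (adjusted p = 0.0477). The progestin receptor gene paqr5a rose by 1.53 ± 0.23 (adjusted p = 0.0165). The calls of pck1, cldnb, guca1c and paqr5a were lost in 17, 13, 17 and 2 of 20 fits. That of guca1c was also lost in 7 of 8 other settings, and those of pck1 and cldnb with the slide block.

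Against untreated fish 54 probes passed for goldfish microbes on zebrafish food, 7 higher and 47 lower (1 and 40 after quantile normalization, 0 and 39 after plain subtraction), and 44 with the slide block. The count was 32, 16 and 18 without untreated replicates 2, 3 and 4, and 25 without treated replicate 1. For zebrafish microbes on goldfish food 32 passed, 6 higher and 26 lower (21 and 41 in the processed values of the series), and 0 with the slide block. That count was 13, 2 and 1 without untreated replicates 1, 3 and 4, and 63, 0, 0 and 1 without treated replicates 1, 2, 3 and 4. For both changes 1235 passed, 652 higher and 583 lower, and 718 with the slide block. That count was 643, 765, 399 and 637 without untreated replicates 1, 2, 3 and 4, and 300 and 703 without treated replicates 1 and 4.

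For all treated groups together against untreated fish 69 probes passed, 15 higher and 54 lower (4 and 40 after plain subtraction), and 21 with the slide block. The count was 14, 23, 8 and 2 without untreated replicates 1, 2, 3 and 4. It was 45, 31, 11 and 20 without replicates 1, 2, 3 and 4 of zebrafish food with zebrafish microbes, and 27 and 24 without replicates 2 and 3 of zebrafish food with goldfish microbes. It was 15 and 18 without replicates 2 and 3 of goldfish food with zebrafish microbes, and 28 and 24 without replicates 1 and 3 of goldfish food with goldfish microbes.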

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

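Of the tests in this part, the ovary marker score as a covariate, the slide as a block and the arms of the clock were chosen only after the result was seen. The other covariates were chosen after seeing the data but before those tests were run.

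In 13 of 195 sets of 4 arrays of a group, 1 array stood far from the other 3, where chance sets apart about 1 in 20. Replicate 4 of goldfish food with zebrafish microbes stood apart in 5 values. Its 75th percentile was 199.6 (1042.2 to 1150.04 on the others), its oocyte and ovary score 1.25 (-0.88 to -0.78), its skeletal muscle score 1.36 (-0.41 to -0.36), its goblet cell score -0.25 (0.20 to 0.29) and its score of lysosome-rich enterocytes -0.11 (0.36 to 0.44). Replicate 3 of zebrafish food with goldfish microbes had an oocyte and ovary score of 0.89 (-0.47 to -0.35) and a heat shock score of 0.0823 (-0.36 to -0.31), and replicate 4 of that group a proteasome score of -0.58 (0.11 to 0.15). Replicate 1 of goldfish food with goldfish microbes had a pancreatic enzyme score of 0.68 (0.31 to 0.37) and a transporter score of 0.45 (0.22 to 0.24). Replicate 3 of zebrafish food with zebrafish microbes had a bile acid score of -1.34 (-0.20 to 0.01). Untreated replicate 4 had an acute inflammation score of -0.24 (0.46 to 0.50), and untreated replicate 1 a cell cycle score of 0.49 (-0.10 to -0.09).

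The effect of the food differed between the microbiomes in 13 lists by camera with its preset correlation, given as medians. They were pancreatic digestive enzymes (1.65), oocytes and ovary (1.51), brush border hydrolases (0.66), lipid absorption (0.59), mitochondrial genes (0.56), xenobiotic response (0.52), the clock (0.45), fatty acid oxidation (0.44), macrophages and neutrophils (-0.36), T and NK cells (-0.53), acute inflammation (-0.71), cholesterol synthesis and uptake (-1.75) and liver (-2.22). With an estimated correlation none passed (lowest adjusted p 0.281).

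Cell cycle genes were lower on goldfish food, with a score difference of -1.10 (95% interval -1.45 to -0.76). With the oocyte and ovary score as a covariate it was -1.07 (-1.42 to -0.71), with array brightness as a covariate -1.14 (-1.44 to -0.84), and with the slide as a block -1.11 (-1.47 to -0.74). These values argue against ovary tissue, array brightness and slide as the whole cause. A difference between tanks stays open because tank and food are confounded.

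Cholesterol genes were lowest with goldfish food and goldfish microbes together, with an interaction of the score of -1.89 (95% interval -3.04 to -0.73). With the liver score as a covariate it was -1.89 (-3.15 to -0.64), with array brightness as a covariate -1.78 (-2.79 to -0.77), and with the slide as a block -1.68 (-2.81 to -0.54). These values argue against liver tissue, array brightness and slide as the whole cause. The tank of that group stays open, since 1 group and its tank cannot be told apart.

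Clock genes were higher on goldfish food, and another hour of sampling or feeding could move them. The repressor and output arm (11 of 11 genes above 0, 6 of them called) had a mean difference of 0.89, the positive arm differed by -0.09 (5 of 9 genes below 0; exact permutation p = 0.557), and the difference of the arms was 0.975 (exact permutation p = 0.00155 over 12870 splits). With zebrafish microbes the arms differed by 0.50 and 0.19 between foods and their difference was 0.316 (exact permutation p = 0.2 over 70 splits). With goldfish microbes the values were 1.28, -0.36 and 1.63 (exact permutation p = 0.0286, the smallest that 70 splits can give; 0.0571 for the positive arm). An hour shift predicts arms that move in opposite directions. The positive arm was mixed, so the values do not decide between an hour shift and another effect of the food. Sampling hours are not given in the sources used.

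Other splits of the arrays into groups of the same sizes were counted, the real split included. For the procedure 1 of 35 splits gave as many probes (real 11, highest other 1), for the microbiome 1 of 100 (473, highest other 4), and for the food 1 of 100 (1548, highest other 7). The share was 1 of 35 for the combined change (1368, highest other 2). For the microbiome it was 1 of 35 on zebrafish food (9, other 4) and goldfish food (177, other 0). For the food it was 1 of 35 with zebrafish microbes (108, other 2) and goldfish microbes (1075, other 2). Against untreated fish 1 of 35 did for goldfish microbes on zebrafish food (54, highest other 50), 1 of 35 for zebrafish microbes on goldfish food (32, highest other 1), 1 of 35 for both (1235, highest other 2), and 1 of 100 for all treated groups (69, highest other 26). The real split gave the most, but 1 of 35 is the lowest share possible. Splits for food and microbiome shuffled both factors, so they cannot test 1 alone. For goldfish microbes on zebrafish food against untreated fish another split came close. These splits ignore the slide. With the slide as a block the counts were 0 for the food with zebrafish microbes and 0 for zebrafish microbes on goldfish food against untreated fish. Over the 108 and 32 probes called there, the median absolute difference was 2.01 and 2.21 without the block and 1.99 and 2.26 with it. The median standard error was 0.35 and 0.35 without it and 0.38 and 0.35 with it, all 108 and 32 kept their sign, and the smallest adjusted p was 0.0567 and 0.0575. The calls ended while the differences hardly moved, in a fit with 11 in place of 15 residual degrees of freedom. For the interaction the real count was 0, so 100 of 100 splits gave as many by construction (highest other 3) and this count says nothing on chance.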

How the results depend on the processing

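Plain background subtraction, the fit without 2 arrays and the score of a list per array were chosen after seeing the data. Counts are of probes called. In what follows, a count not given lay within 1.5 times the reported one, and the cause of a change was not tested unless stated.

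Normexp correction lifted 7 of 20 arrays, whose 25th percentile became 365.21 to 2642.33 against 60 to 125 by subtraction, so its fit failed there and its values say little about the data. It gave 0 probes for the procedure, 0 for the microbiome, 3 for the food, 1 for the combined change, 0 and 0 for the microbiome on zebrafish and goldfish food, and 0 and 4 for the food with zebrafish and goldfish microbes. It also gave 0, 0 and 2 for goldfish microbes, goldfish food and both against untreated fish, and 0 for all treated groups. In the comparison of microbiomes arl16 (-0.11), p2rx4b (-0.32), bbc3 (-0.0715) and ctss1 (-0.14) reversed. Lists that reversed for the procedure were pancreatic enzymes (adjusted p = 0.931), unfolded protein response (0.836), ribosomal proteins (0.271) and proteasome (0.0715). Those for the microbiome were lipid absorption (0.937), gluconeogenesis and glycolysis (0.00206), amino acid breakdown (0.00632), interferon (0.988), antioxidant (0.0936), unfolded protein response (0.988), ribosomal proteins (1.61e-07), mitochondrial genes (9.56e-05) and proteasome (0.109). The correlations of the simple effects became 0.0881 (rank -0.0109) for the food and 0.254 (rank 0.400) for the microbiome.

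Quantile normalization gave 252 probes for the microbiome and 21 for zebrafish microbes on goldfish food against untreated fish. For the procedure, pancreatic enzymes (0.806) and ribosomal proteins (0.0212) reversed. With no filter the microbiome on zebrafish food gave 2. The stricter filter, which tests fewer probes, gave 280 for the microbiome on goldfish food, 92 and 82 for goldfish microbes and for goldfish food against untreated fish, and 128 for all treated groups. The processed values of the series gave 62 for zebrafish microbes on goldfish food against untreated fish.

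Plain subtraction gave 155 for the microbiome, 1011 for the food, 712 for the combined change, 5 for the microbiome on zebrafish food, 26 for the food with zebrafish microbes, 799 for both changes against untreated fish and 44 for all treated groups. The correlation for the food became 0.220 (rank 0.178), and the rank correlation for the microbiome 0.0801. Without the dimmest array and the array with the noisiest repeat spots the counts were 977 for the microbiome, 2305 for the combined change, 23 for the microbiome on zebrafish food, 0 for the food with zebrafish microbes, 124 for goldfish microbes on zebrafish food and 2 for zebrafish microbes on goldfish food against untreated fish. The correlations were then 0.298 (rank 0.246) for the food and 0.138 (rank 0.208) for the microbiome.

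With the slide as a block the counts were 157 for the microbiome, 902 for the combined change, 5 and 57 for the microbiome on zebrafish and goldfish food, 0 and 618 for the food with zebrafish and goldfish microbes, 0 and 718 for zebrafish microbes on goldfish food and for both changes against untreated fish, and 21 for all treated groups. The compared groups alone gave 19 for the procedure, 145 for the microbiome, 633 for the combined change, 0 and 0 for the microbiome on zebrafish and goldfish food, 2 and 30 for the food with zebrafish and goldfish microbes, and 0, 0 and 377 for goldfish microbes, goldfish food and both against untreated fish. That fit has fewer arrays to estimate the spread.

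The labels do not say whether replicate numbers pair samples. The numbers are those of the scanner files, which differ from the processed values for 13 of 20 samples, so what follows holds for that numbering alone. Of 40 same-number pairs 12 had a correlation of deviations over 0.1 (median 0.0333, -0.248 to 0.363), against 24 of 120 other pairs (median -0.0129). On the same slide 9 of 30 did, against 27 of 130 on different slides. Of 20 arrays 10 correlated best with their own number and 14 with their own slide. With the replicate block the counts were 5 for the microbiome on zebrafish food, 1 for zebrafish microbes on goldfish food against untreated fish and 45 for all treated groups. They were 13 for the procedure, 432 for the microbiome, 1429 for the food and 0 for the interaction.

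Without 1 array, the counts ran from 1 to 11 for the procedure, 83 to 823 for the microbiome, 1001 to 1742 for the food, 0 to 3 for the interaction, and 214 to 1120 for the combined change. They ran from 0 to 45 and 17 to 168 for the microbiome on zebrafish and goldfish food, and 0 to 146 and 275 to 992 for the food with zebrafish and goldfish microbes. Against untreated fish they ran from 16 to 69, 0 to 63 and 300 to 1016 for goldfish microbes, goldfish food and both, and 2 to 88 for all treated groups. The correlations ran from 0.0534 to 0.237 (rank 0.0374 to 0.237) for the food and -0.117 to 0.0755 (rank -0.0575 to 0.181) for the microbiome.

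Of 54 calls of lists, 51 were lost with an estimated correlation and 35 as 1 score per array, 2 with the slide as a block and 0 with the replicate block. Of the calls of 170 values of named genes, 166 were lost with normexp, 66 each with the slide as a block and with the compared groups alone, 46 with plain subtraction, 35 without 2 arrays, 30 with the replicate block, 25 with quantile normalization, 20 with no filter and 19 with the processed values of the series. Of the other values some became calls, 14 with the stricter filter, 12 without 2 arrays, 6 with the replicate block, 4 each with plain subtraction and the processed values, 3 with the slide, 2 with the compared groups alone and 1 with quantile normalization. Over the probes called for the food and the microbiome the median absolute difference was 1.18 and 1.07 without the slide as a block, and 1.17 and 1.05 with it. Signal over background limits what can be seen: 29099 of the 40300 probes were well above it on all 20 arrays, and a gene near it on 1 side has a bound alone.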

Other observations

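The groups of genes in this part were chosen after the values were seen.

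Some genes moved with both the food and the microbiome, in opposite directions or in the same one. Of the probes called, 40 were called in both comparisons (23 genes), where 18.2 were expected from the sizes of the lists. The lipid and glucose genes pck1, cidec and cebpa rose with goldfish food by 1.56, 1.44 and 1.07 and fell with goldfish microbes by 1.98, 1.83 and 1.39. The same held for mid1ip1l, for a regulator of fat synthesis (1.55 and -0.94), gclm (0.75 and -1.13) and serpinh1b (0.95 and -0.89). The fall of mid1ip1l and the rise of gclm held in 6 of 8 arrays each. Without 1 array the calls on food were lost in 12 of 16 fits for pck1 and 10 for gclm, and those on microbes in 6 for pck1, 12 for mid1ip1l and 9 for serpinh1b. The slide block ended the calls of pck1 on both, of gclm on food and of mid1ip1l and serpinh1b on microbes. In all 17 probes were higher with goldfish food and lower with goldfish microbes (3.33 expected), and 2 the other way (5.90 expected).

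In the same direction, 12 probes were higher in both comparisons (5.09 expected) and 9 were lower in both (3.86 expected). The repressor gene nr0b2a rose by 2.74 and 2.66 and cebpd by 1.13 and 1.16 (8 and 7 of 8 arrays), while the sterol genes hmgcs1 (-1.94 and -1.72), sqlea (-2.19 and -1.99) and hmgcra (-1.54 and -1.58) fell in both. They were lower in 6 of 8 arrays for food, and in 6, 5 and 5 of 8 for microbes, where the calls were lost in 6, 11 and 10 of 16 fits and with the slide as a block. The call of hmgcra on food was lost with that block too. The 2 comparisons use the same 16 arrays and share 1 estimate of the spread of each probe, so the numbers expected for independent lists are a guide alone. The sterol genes were low and cebpd was high (4.71, against 2.43 to 2.90 in the other treated groups) in the group with both changes, so their 2 effects are not separate findings.

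The genes rbp4l (3.83), saga (2.39) and crygm3 (2.26), known from the eye, rose on goldfish food. The call of saga was lost with plain subtraction and without 2 arrays. Of 44 crystallin genes 1 rose and 33 lay above 0 (median 0.28). Of 34 phototransduction genes 2 rose and 21 lay above 0 (median 0.23). Of all 12741 genes 352 rose by any of their probes, while the sets were counted by 1 probe per gene. The sets were not tested. In all treated groups against untreated fish guca1c, of the same pathway, fell by 3.10, a call lost in 17 of 20 fits without 1 array and with the slide as a block.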
